A study of Mus musculus with 9 samples.

How the data were processed

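Total RNA of NIH-CAR cells was measured on 9 Affymetrix expression arrays, 3 in each of 3 groups. NIH-CAR cells are a clone of NIH-3T3 mouse fibroblasts that carries the coxsackievirus and adenovirus receptor, which lets adenoviral vectors enter. The groups were cells given an adenovirus with no insert and then vehicle (empty vector), cells given an adenovirus encoding full-length PPARγ2 and then rosiglitazone, and cells given an adenovirus encoding PPARγ without its A/B-domain and then rosiglitazone. Group and replicate number were taken from the sample titles. Per the labels' protocols, the virus was left on for 2 h, rosiglitazone was added at 1 µM, and RNA was primed with oligo(dT) before labelling. Cells were at passage 12. The design text speaks of separate experiments but does not say which arrays belong to which, and no date or batch was given.

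The deposited table held 1 log2 value per probe set and array for 45101 probe sets, made by the authors with RMA in the R package affy under R 2.5.0, per the submitters' processing notes. The base of the logarithm was not stated. It was read from the values: the antilog to base 2 was a whole multiple of 0.01, within 0.01 of that unit, for at least 99.858% of the values of every array. Array medians ran from 6.68 to 6.90 and upper quartiles from 8.21 to 8.26, so the arrays were not exactly quantile-equal. Across all arrays 9 values were exactly 0, and the highest was 14.82. Correlations between arrays across probe sets ran from 0.957 to 0.991, and no pair of arrays held duplicate values. The table carried no detection calls, so expressed and unexpressed probe sets could not be told apart by a stated limit. For arrays there is no read depth, and the number of arrays limits the precision. The median standard error of a difference between groups was 0.158 on the log2 scale.

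Probe sets were named from the platform annotation. Of the 45101 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 64 were Affymetrix controls, 13 of them with a symbol. Entrez identifiers of 34741 single-gene probe sets were found in the RefSeq gene table of GRCm38.p6, which changed 0 symbols and was used only for names. No genome was used, so no coordinates are given. Control probe sets and those with no symbol or several were left out of the comparisons. For each gene the probe set with the highest mean over the 9 arrays was kept, which gave 18193 genes, 9010 of them with more than 1 probe set.

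Values were used as deposited. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, figures were drawn with matplotlib 3.10.9, and models were fitted in R 4.3.3. Differences were tested with limma 3.58.1 (lmFit, contrasts and eBayes, two-sided) in 1 fit over the 9 arrays with 3 group means and no block, which left 6 residual degrees of freedom and an estimated 3.374 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes. The comparisons were full-length receptor against empty vector, deleted receptor against empty vector, deleted against full-length receptor, and an F test over the 3 groups. The share of the full-length response kept by the deleted receptor was the median, over genes called higher by at least 1 log2 unit, of 100 times the ratio of the fold changes against empty vector on the log2 scale.

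The groups, tests, alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered lipid droplets and lipolysis; fatty acid uptake, oxidation and synthesis; triglyceride and cholesterol synthesis; adipocyte, brown adipocyte and preadipocyte genes; extracellular matrix, contractile, inflammatory, interferon, cell cycle, p53, protein folding stress, oxidative stress, glucose and respiratory chain genes; nuclear receptors; reference genes; and markers of muscle, bone, leukocyte and epithelial or endothelial cells. Each list was tested in each of the 3 comparisons with camera at a preset correlation between genes of 0.01, adjusted over 75 tests, and again with an estimated correlation and with fry. Genes were named if they were among the 10 largest called changes in each direction of a comparison with no overlap between the groups, among the 4 largest called members of a list, or Pparg or Cxadr. The 10 largest and 10 smallest differences between the receptors, among genes at least 1 log2 unit higher with the full-length receptor, were also named. Other genes were chosen after their values were seen.

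Whether equal replicate numbers pair the arrays was checked from the correlation, across genes, of deviations from the group means. The 3 correlations ran from 0.520 to 0.708 between the deleted receptor and empty vector and from 0.297 to 0.531 between the 2 receptors, so those numbers were treated as pairs. The main fit was fixed without a block, so its counts, SE and intervals leave this pairing out. Fits with the number as a block are given where they change a result. The median SE was 0.114 with the block and 0.158 without it. Between the full-length receptor and empty vector they ran from -0.121 to 0.631, so those arrays were treated as sharing only a number.

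On simulated data with 200 of 18193 genes changed, drawn 5 times, the test of full-length receptor against empty vector recovered 11.9% of changes of 0.5 log2 units, 63.0% of 1 and 91.5% of 2. The shares were 10.1%, 65.4% and 93.0% for the deleted receptor against empty vector, and 12.2%, 69.0% and 92.7% between the receptors. False calls made up 3.5%, 4.8% and 3.5% of calls in the 3 comparisons. A simulated kept share of 70% was returned as 69.3%, and one of 100% as 98.9%. Among 75 list tests in 10 simulations with no effect, 0 were called. Genes were simulated as independent, so this does not show how often lists of correlated genes are called at the preset correlation.

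Alternatives tried were the replicate block; filters on dim genes; median subtraction, quantile normalization or cyclic loess; other choices among the probe sets of a gene; other variance priors; array weights; fits on the compared arrays alone; stricter thresholds; and leaving out each array in turn. Tests of the 2 receptors within genes higher in the mean of both receptors against empty vector, the fits without the arrays numbered 3, the choice of 100 genes for each held-out number, the simulated overlap and sign of calls, the splits within a replicate number and the tests of unnamed probe sets were chosen after seeing the data.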

Results

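Transcript levels were measured on 9 arrays of NIH-CAR cells, fibroblasts that adenoviral vectors can enter. PPARγ2 is the nuclear receptor that directs adipocyte differentiation, and rosiglitazone is an agonist that binds and activates it. The A/B-domain is the N-terminal part of the receptor, which holds a ligand-independent activation function. The empty-vector group received vehicle, and both receptor groups received 1 µM rosiglitazone, with 3 arrays in each group. The title of the study asks in which genes the A/B-domain matters for activation. Array medians ran from 6.68 to 6.90. All levels and differences below are on the log2 scale, as mean ± SD over 3 arrays or as a difference with its standard error (SE), and adjusted p-values come from limma unless another test is named. These p-values measure the spread between arrays of 1 cell line.

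Pparg, the gene of the receptor, was at 7.06 ± 0.10 (SD, n = 3) with empty vector, 11.25 ± 0.84 with the full-length receptor and 11.34 ± 0.63 with the deleted receptor. Its single probe set does not separate transgene from endogenous transcript. The arrays numbered 1, 2 and 3 read 10.70, 12.22 and 10.84 with the full-length receptor and 10.74, 12.01 and 11.26 with the deleted receptor. The rise over empty vector was 4.20 (SE 0.41, adjusted p = 0.00191) and 4.28 (SE 0.41, adjusted p = 0.00228). Between the receptors the difference was 0.09, with a 95% interval from -0.83 to 1.01. Cxadr, the gene of the virus receptor, was at 6.38 ± 0.17, 6.41 ± 0.08 and 6.51 ± 0.09 and was not called in any of the 3 comparisons. These levels lay below the lowest array median, 6.68, so they do not show equal amounts of the virus receptor. Over its 5 probe sets the difference between the receptors ran from -0.11 to 0.33.

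The first principal component held 38.1% of the variance across genes and set the arrays numbered 3 apart from the others. Their scores were 42.5 with the full-length receptor, 20.6 with empty vector and 22.3 with the deleted receptor, and the other 6 arrays lay between -21.1 and 0. On the second component, with 22.2% of the variance, they did not lie together. There full-length array 3 was at -21.6, empty-vector array 3 at 26.6 and deleted-receptor array 3 at 20.2. The 18S ribosomal RNA control probe sets averaged 7.59, 8.67 and 8.06 on those 3 arrays and between 10.51 and 12.44 on the other 6.

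The first comparison asked what the full-length receptor with its agonist changed against empty vector with vehicle. Fabp4, the fatty acid binding protein of adipocytes, rose from 5.82 ± 0.37 to 13.42 ± 0.26, by 7.60 (SE 0.47, adjusted p = 0.000237). Lpl, the lipase that frees fatty acids from lipoproteins, rose by 3.86 (SE 0.23), its secreted inhibitor Angptl4 by 3.59 (SE 0.38) and the lipid droplet coat protein Plin2 by 3.04 (SE 0.35). Cpt1a, which controls the entry of fatty acids into mitochondria, rose by 1.73 (SE 0.15, adjusted p = 0.00119). Among genes that fell, the chemokine gene Cxcl5 dropped by 3.05 (SE 0.42, adjusted p = 0.0124), and Dusp6, a phosphatase gene of the ERK pathway, dropped by 2.04 (SE 0.23, adjusted p = 0.0043). In all, 91 genes were higher, Pparg among them, and 28 were lower. With the replicate number as a block, though these arrays were not treated as pairs, 344 were higher and 317 were lower. In each gene named as called here the 3 arrays of one group lay above all 3 of the other, a separation seen in 9.4% of all genes, where chance gives 10%.

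**Figure D1:**
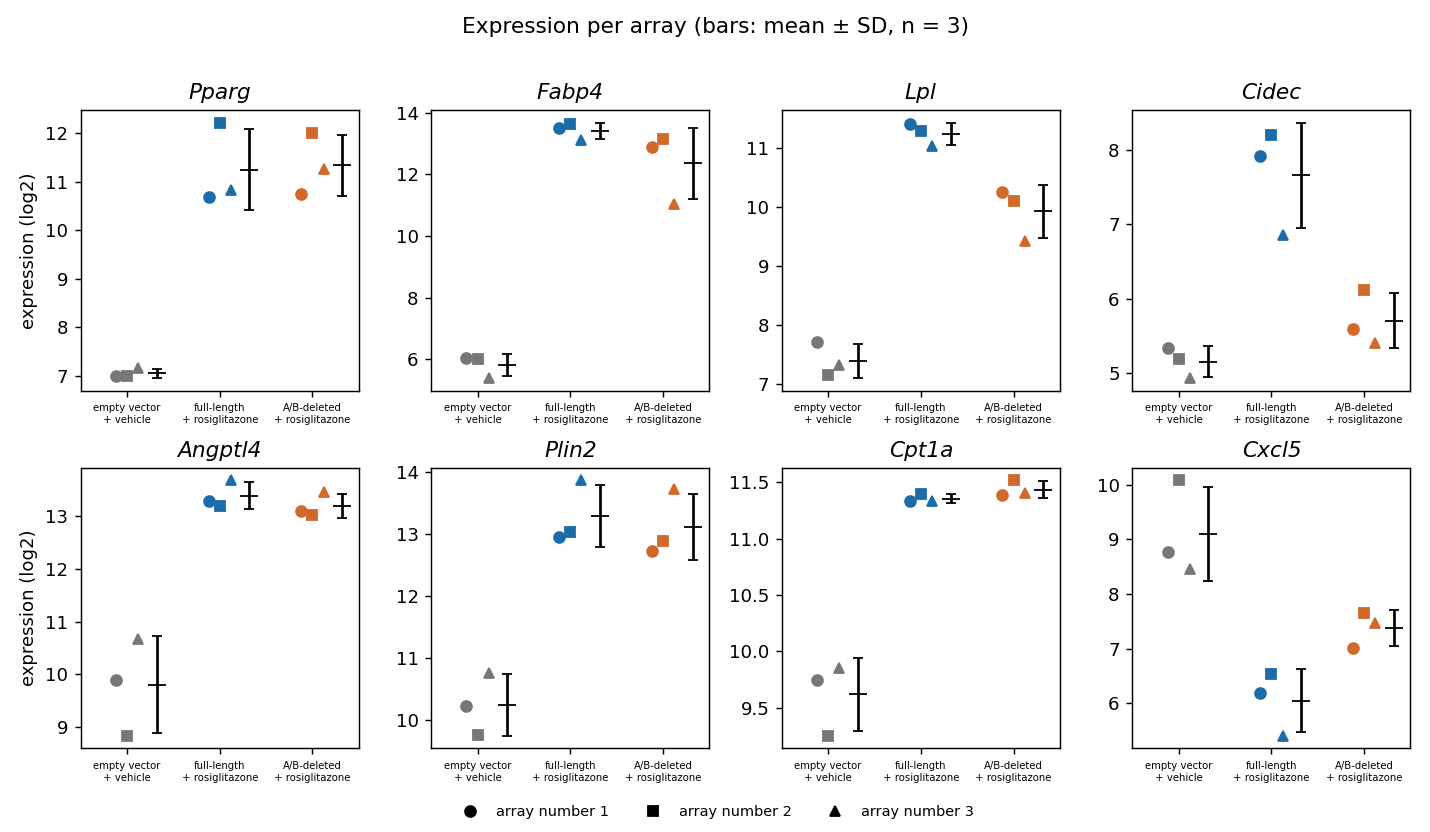
Log2 expression of 8 genes on each array, by group, with marker shape giving the array number and bars giving the mean ± SD (n = 3). Fabp4 lay near 5.82 with empty vector and 13.42 with the full-length receptor, while Cidec lay at 7.66 with the full-length and 5.70 with the deleted receptor.

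Other large increases were those of Kank3 (3.54), Pkp2 (3.29), Mgst1 (3.27), Btg2 (2.60) and Cdk18 (2.51). Pkp2 encodes a desmosomal plaque protein and had the smallest adjusted p, 6.65e-05. The probe sets of some genes disagreed. The increase ran from 0.02 to 3.29 over the 4 probe sets of Pkp2, from 0.22 to 3.27 over the 2 of Mgst1 and from 0.44 to 3.54 over the 3 of Kank3. Other large decreases were those of Ankrd1 (-1.97), Cebpd (-1.97), Egr1 (-1.82), Errfi1 (-1.80), Efnb2 (-1.79), Rgs2 (-1.72), Tnfaip6 (-1.68) and Pcdh18 (-1.60). Egr1 is an immediate-early transcription factor gene, Errfi1 encodes a feedback inhibitor of EGF receptor signalling and Cebpd encodes a transcription factor of early adipogenesis. The 4 probe sets of Rgs2 ran from -1.72 to 0.10 and the 4 of Efnb2 from -1.79 to -0.34. Among genes named below, the 2 probe sets of Acot2 ran from 0.37 to 1.59 and the 2 of Etfdh from 0.29 to 1.00. The 3 of Vcam1 ran from -1.57 to -0.26 and the 2 of Cav2 from -1.13 to -0.17. Not every gene whose probe sets disagreed is listed.

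The list of mitochondrial and peroxisomal fatty acid oxidation genes was higher, with a median of 0.38 over 43 genes (camera adjusted p = 2.41e-17; adjusted p = 0.102 with an estimated correlation). Of these genes 5 rose and 38 were not called, and 15 rose when adjusted over the list alone. The 5 were Cpt1a, Acot2 (1.59), Ech1 (1.28), Etfdh (1.00) and Cpt2 (0.98, named after its value was seen), enzymes of fatty acid import, thioester hydrolysis and oxidation. Fatty acid uptake and binding genes were higher (camera adjusted p = 1.94e-06; adjusted p = 0.100 with an estimated correlation), and 3 of 20 rose, Fabp4, Lpl and Angptl4, or 4 when adjusted over the list alone. Oxidative stress and xenobiotic genes were higher (camera adjusted p = 2.18e-06; adjusted p = 0.100 with an estimated correlation). In that list 3 of 33 rose, Mgst1, Ephx2 (1.23) and Aldh9a1 (1.16), and 8 rose and 1 fell when adjusted over the list alone. Lipid droplet and lipolysis genes were higher (camera adjusted p = 0.0031; adjusted p = 0.144 with an estimated correlation). Of these 20 genes Plin2, Cidec (2.51), which acts in droplet fusion, and Fitm2 (1.77), which acts in droplet formation, rose and Rgs2 fell, with 5 higher and 1 lower when adjusted over the list alone. Triglyceride synthesis genes were higher (camera adjusted p = 0.00913; adjusted p = 0.324 with an estimated correlation), with Pcx (1.89), pyruvate carboxylase, the 1 of 18 that rose over all genes and 1 when adjusted over the list alone.

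Contractile and serum response genes were lower (camera adjusted p = 0.00205; adjusted p = 0.317 with an estimated correlation). Ankrd1 was the 1 of 22 that fell, and 4 fell and 1 rose when adjusted over the list alone. Preadipocyte and anti-adipogenic regulators (camera adjusted p = 0.00862; adjusted p = 0.663 with an estimated correlation) and protein folding stress genes (camera adjusted p = 0.00956; adjusted p = 0.722 with an estimated correlation) were lower, with 0 of 26 and 0 of 30 members called by limma. Adjusted over the list alone, 1 preadipocyte gene and 0 folding stress genes fell. With the block, limma over all genes called 5 preadipocyte genes and 1 folding stress gene lower. Adipocyte identity genes were not called as shifted (camera adjusted p = 0.38). Their median of 0.11 lay at the 99.86 percentile of 10000 random lists of equal level, which treat genes as independent, so a shift stays open. Of 28 members Pparg rose and Cebpd and Cav2 (-1.13), a caveolin gene, fell, as they did when adjusted over the list alone. NF-kB and inflammatory genes (adjusted p = 0.11) had 2 of 32 members lower, Cxcl5 and the adhesion molecule gene Vcam1 (-1.57), and 1 higher and 3 lower when adjusted over the list alone. In other uncalled lists Fads3 (1.34), Trim25 (1.59) and Btg2 rose and Rarg (-0.70) fell. The camera adjusted p was 0.101 for fatty acid synthesis, 0.3 for cholesterol synthesis, 0.219 for brown adipocyte, 0.979 for extracellular matrix, 0.908 for interferon, 0.3 for cell cycle and 0.892 for p53 genes. It was 0.0947 for glucose metabolism, 0.3 for respiratory chain, 0.602 for nuclear receptor and 0.999 for reference genes. Marker lists of other cell types had 0.831 for muscle, 0.999 for bone and cartilage, 0.63 for leukocytes and 0.676 for epithelial and endothelial cells. In the interferon, p53, muscle, bone and reference lists, none of them called, the median, mean and test differed in sign. Of 8 list calls by camera 0 held with an estimated correlation, and fry called lipid droplet, uptake, oxidation and oxidative stress genes (adjusted p = 0.0439, 0.0376, 0.0439 and 0.0437).

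Leaving out 1 array moved the count of higher genes to 53 without full-length replicate 1, 44 without full-length replicate 2, 49 without empty-vector replicate 1 and 48 without empty-vector replicate 2, and the count of lower genes to 18, 13 and 14 without full-length replicate 1, full-length replicate 2 and empty-vector replicate 2. Receptor and agonist changed together, so neither can be read alone. The calls of Btg2, Ech1 and Pcx were lost without any 1 of full-length replicates 1 and 2 or the 3 empty-vector arrays, with adjusted p up to 0.0794, 0.138 and 0.137, and those of Ech1 and Pcx also without deleted-receptor replicate 1. Efnb2 was lost without full-length replicate 1 or 2 or empty-vector replicate 2 or 3 (up to 0.0982), and Errfi1 without full-length replicate 2 or empty-vector replicate 1 (up to 0.0668). Rgs2 was lost without full-length replicate 1 or empty-vector replicate 2 (up to 0.0557). Cebpd, Cav2 and Pcdh18 were lost without full-length replicate 2, at 0.055, 0.0745 and 0.0583, and Rarg without any 1 array but full-length replicate 3 (up to 0.204). Without the 3 arrays numbered 3, a fit chosen after seeing the data, 121 genes were higher and 35 lower, and Cav2, Errfi1, Rarg and Rgs2 were not called (adjusted p = 0.0663, 0.0647, 0.059 and 0.0525). With only the 6 compared arrays Cxcl5 (0.0537), Ech1 (0.0549), Rgs2 (0.0592), Cav2 (0.0527) and Rarg (0.155) were not called. With the mean of a gene's probe sets Cebpd (-1.64, 0.108) and Rarg (-0.64, 0.222) were not called, and Rarg was not called after median subtraction (0.0539).

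The second comparison set the receptor without its A/B-domain against empty vector. Fabp4 rose by 6.54 (SE 0.47, adjusted p = 0.000911), Angptl4 by 3.40 (SE 0.38, adjusted p = 0.00737), Pkp2 by 2.98 (SE 0.16, adjusted p = 0.000165) and Lpl by 2.54 (SE 0.23, adjusted p = 0.00181). Plin2 rose by 2.87, Kank3 by 2.87, Mgst1 by 2.38, Mob3b by 2.26 and Gm20559 by 2.25. Probe sets disagreed here too, as in the 2 of Mob3b, which ran from 0.32 to 2.26. The arrays of each of these genes were separated by group, as in 7.9% of all genes, where chance gives 10%. Of the 31 called genes 29 were higher and 2 were lower, Socs5 (-0.98), which encodes a suppressor of cytokine signalling, and Cdc42ep1 (-0.83), which encodes an effector of the GTPase CDC42. With the replicate number as a block 120 were higher and 46 were lower. The block added calls of Dusp6 (-1.42, adjusted p from 0.0697 to 0.0221), Egr1 (-1.31, 0.0697 to 0.0203), Ankrd1 (-1.52, 0.0697 to 0.024), Tnfaip6 (-1.15, 0.0697 to 0.0199), Cebpd (-1.44, 0.109 to 0.0168) and Rgs2 (-1.37, 0.109 to 0.0179). It also added Ech1 (1.26, 0.0697 to 0.00506), Fitm2 (0.96, 0.109 to 0.0263), Btg2 (1.69, 0.261 to 0.02), Errfi1 (-1.21, 0.21 to 0.0239), Efnb2 (-1.17, 0.285 to 0.0263), Cav2 (-0.68, 0.341 to 0.0219) and Rarg (-0.60, 0.207 to 0.0291). Cxcl5 was at -1.72 (adjusted p = 0.401) and Cidec at 0.55 (adjusted p = 1.00), neither called with the block. Without the 3 arrays numbered 3, a fit chosen after seeing the data, 49 were higher and 6 lower.

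Fatty acid oxidation genes were higher (camera adjusted p = 1.21e-18; adjusted p = 0.100 with an estimated correlation). Cpt1a (1.81), Acot2 (1.56) and Etfdh (0.91) were the 3 of 43 that rose, against 15 when adjusted over the list alone, and with the block these counts were 11 and 22. Fatty acid uptake genes were higher (camera adjusted p = 1.94e-06; adjusted p = 0.100 with an estimated correlation), with the same 3 genes called as for the full-length receptor and 4 when adjusted over the list alone. With the block 4 were higher and 1 was lower, either way. Oxidative stress and xenobiotic genes were higher (camera adjusted p = 4.81e-07; adjusted p = 0.100 with an estimated correlation), with Mgst1 and Aldh9a1 (1.01) called and 3 when adjusted over the list alone. With the block 5 of 33 were higher, or 13 higher and 1 lower when adjusted over the list alone. Lipid droplet genes were higher (camera adjusted p = 0.0031; adjusted p = 0.144 with an estimated correlation). Plin2 was the 1 member that rose, and 3 rose and 1 fell when adjusted over the list alone. With the block 2 were higher and 1 lower, or 5 and 2 when adjusted over the list alone. Fatty acid synthesis genes (camera adjusted p = 0.00862; adjusted p = 0.585 with an estimated correlation) were higher with Fads3 (1.16), a desaturase family gene, called over all genes and 1 when adjusted over the list alone. Triglyceride synthesis genes (camera adjusted p = 0.0411; adjusted p = 0.513 with an estimated correlation) were higher with 0 called either way, or 2 higher when adjusted over the list alone with the block. Contractile genes (camera adjusted p = 0.00876; adjusted p = 0.455 with an estimated correlation) were lower with 0 called and 2 lower when adjusted over the list alone. With the block 3 of 22 were lower, or 5 when adjusted over the list alone. Protein folding stress genes (camera adjusted p = 0.0378; adjusted p = 0.783 with an estimated correlation) were lower with 0 called either way. Trim25 (1.42) was the interferon list's 1 called gene. In other uncalled lists the block moved the called members from 0 to 3 higher for extracellular matrix, 2 higher and 2 lower for NF-kB, 1 higher and 1 lower for p53 and 1 higher for glucose metabolism genes. It moved them from 1 higher to 1 higher and 2 lower for adipocyte identity and 1 higher and 1 lower for nuclear receptor genes. Adjusted over the list alone with the block, higher and lower members numbered 4 and 3 for extracellular matrix, 3 and 6 for NF-kB, 4 and 4 for p53, 3 and 3 for adipocyte identity, 4 and 3 for nuclear receptor, 3 and 0 for cell cycle and 1 and 0 for respiratory chain genes. With the block the muscle marker list went from 0.0555 to 0.045, lower, and the respiratory chain list from 0.111 to 0.0397, higher, and neither was called with an estimated correlation (adjusted p = 0.713 and 0.792 with an estimated correlation). Median subtraction ended the calls of the triglyceride synthesis (0.0506) and protein folding stress lists (0.0558). It added the muscle marker list, lower (0.0341; adjusted p = 0.398 with an estimated correlation). Fry called the uptake list alone (adjusted p = 0.0437).

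The count of higher genes was 19 without empty-vector replicate 1, 17 without empty-vector replicate 2, 19 without deleted-receptor replicate 1 and 17 without deleted-receptor replicate 2. The count of lower genes was 0 without full-length replicate 2, any 1 empty-vector array or deleted-receptor replicate 1 or 2, 1 without full-length replicate 1 or deleted-receptor replicate 3, and 4 without full-length replicate 3. The call of Plin2 was lost without empty-vector replicate 1 or 2 or deleted-receptor replicate 2, with adjusted p up to 0.0748. Kank3 and Mgst1 were lost without empty-vector replicate 1 or 2 or any 1 deleted-receptor array (up to 0.162 for each), and Kank3 also without empty-vector replicate 3. Fads3 and Socs5 were lost without full-length replicate 1 or 2, any 1 empty-vector array or deleted-receptor replicate 1 or 2 (up to 0.247 and 0.162), and Cdc42ep1 without any 1 array but full-length replicate 3 (up to 0.209). Etfdh was lost without any 1 empty-vector array or deleted-receptor replicate 1 or 2 (up to 0.113). Aldh9a1 was lost without full-length replicate 2, empty-vector replicate 1 or 2 or deleted-receptor replicate 2 or 3 (up to 0.127). Preferring probe sets not marked as matching several transcripts ended the calls of Gm20559 (0.48, adjusted p = 1.00) and Pkp2 (2.19, 0.118), and the mean of a gene's probe sets ended those of Kank3 (1.72, 0.0558), Etfdh (0.54, 0.178) and Cdc42ep1 (-0.49, 0.418). With only the 6 compared arrays Mgst1 (0.051), Etfdh (0.0607), Aldh9a1 (0.0808), Fads3 (0.0818), Cdc42ep1 (0.0818) and Socs5 (0.0836) were not called. Other scalings ended the calls of Fads3 and Cdc42ep1 (up to 0.0666 and 0.0972), and leaving out the arrays numbered 3 those of Etfdh (0.0694) and Cdc42ep1 (0.0727).

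All 29 higher genes of the deleted receptor, Pparg among them, and both lower genes were also called with the full-length receptor. For independent lists 0.145 and 0.00308 would be expected, a value that leaves out the shared control arrays. In 100 simulations against the same controls, run after seeing the data, the effects of the deleted receptor were moved to random genes. It then had a mean of 22.3 higher and 1.25 lower calls, of which 0.25 and 0.17 were shared and at most 2 and 2 in 1 simulation. The full-length receptor had 62 higher and 26 lower calls of its own, and all 91 higher and all 28 lower genes had the same sign with the deleted receptor. Simulated with the deleted receptor unchanged, 54.7% and 57.4% of the full-length calls had the same sign. Across genes, which are not independent replicates, the fold changes of the receptors correlated at r = 0.759. Simulated unchanged groups against the same controls gave 0.499 ± 0.016 (SD, 100 simulations). The covariance was 0.0415 against a simulated 0.026, a difference of 0.0155, and 68.6% of genes had the same sign against a simulated 66.7%. That simulation treats arrays as independent. With what same-numbered arrays share, estimated from their deviations, unchanged groups would give a covariance of 0.0187 and r = 0.617. Because 3 control arrays cannot be split into 2 sets of at least 2, part of the excess over independent lists may come from the shared controls. For the higher genes that part was small in the simulations against the same controls, where at most 2 were shared against the observed 29. For the lower genes at most 2 were shared against the observed 2, so the simulations decide nothing there. With the block the lists shared 117 of 120 higher and 46 of 46 lower genes, against 2.27 and 0.802 expected for independent lists. With effects moved to random genes a mean of 2.49 of 74.3 higher and 1.26 of 24.9 lower genes was shared. Both receptor groups received rosiglitazone and the controls did not. Any effect of the agonist alone would therefore be shared as well, and it was not tested apart.

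**Figure D2:**
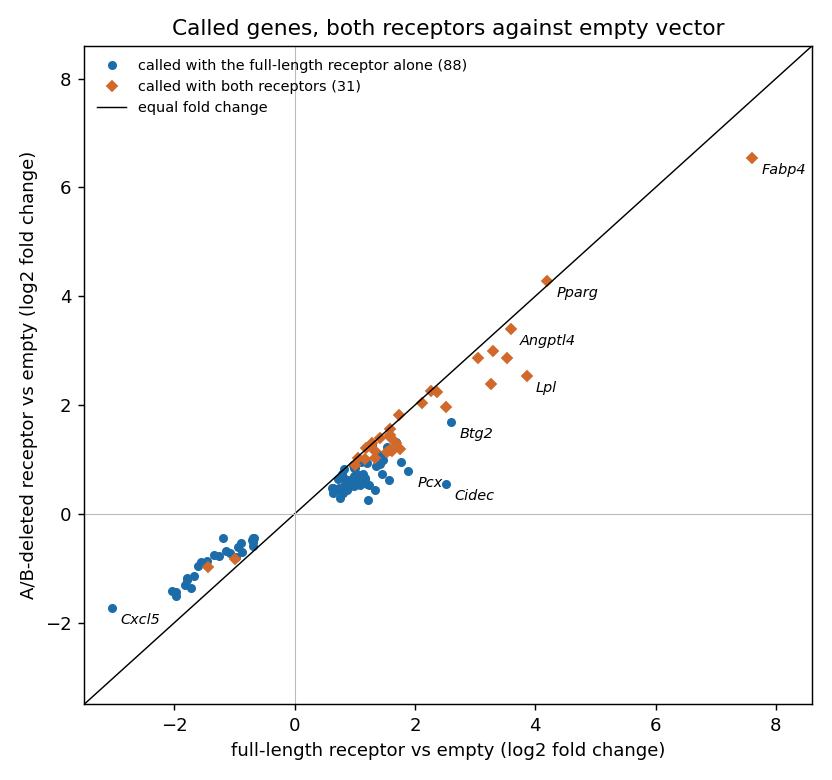
Log2 fold change against empty vector with the full-length receptor (x axis) and the deleted receptor (y axis) for the 119 genes called with the full-length receptor, 88 of them with that receptor alone and 31 with both. The line marks equal change, and all 119 genes had the same sign with both receptors.

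The third comparison, deleted against full-length receptor with agonist in both arms, addressed the A/B-domain directly. Lpl was at 11.25 ± 0.19 with the full-length and 9.93 ± 0.44 with the deleted receptor, a difference of -1.32 (95% interval -1.84 to -0.80, limma adjusted p = 0.871 over all genes). Cidec differed by -1.96 (-2.69 to -1.23, adjusted p = 0.871) and Adamts4, which encodes an extracellular protease, by -0.96 (-1.19 to -0.73, adjusted p = 0.08). Cpt1a differed by 0.08 (-0.27 to 0.43) and Plin2 by -0.18 (-0.96 to 0.60). Over all 18193 genes limma called 0 higher and 0 lower, with and without the block. An unadjusted p under 0.05 was seen in 277 genes, or 786 with the block, where 910 would be expected by chance. For the deleted receptor against empty vector these counts were 689 and 1790. With counts below chance, these p-values cannot be taken as evenly spread when nothing changes. The 0 calls therefore do not show that the receptors act alike. With array weights 0 genes were higher and 2 were lower, Cidec and Adamts4 (adjusted p = 0.00833 for each), and without full-length replicate 3 the 1 gene called was Cidec (adjusted p = 0.036). Over all alternatives the adjusted p ran from 0.00833 to 1.00 for Cidec and to 0.773 for Adamts4. Separated groups were seen in 5.2% of all genes, where chance gives 10%.

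**Figure D3:**
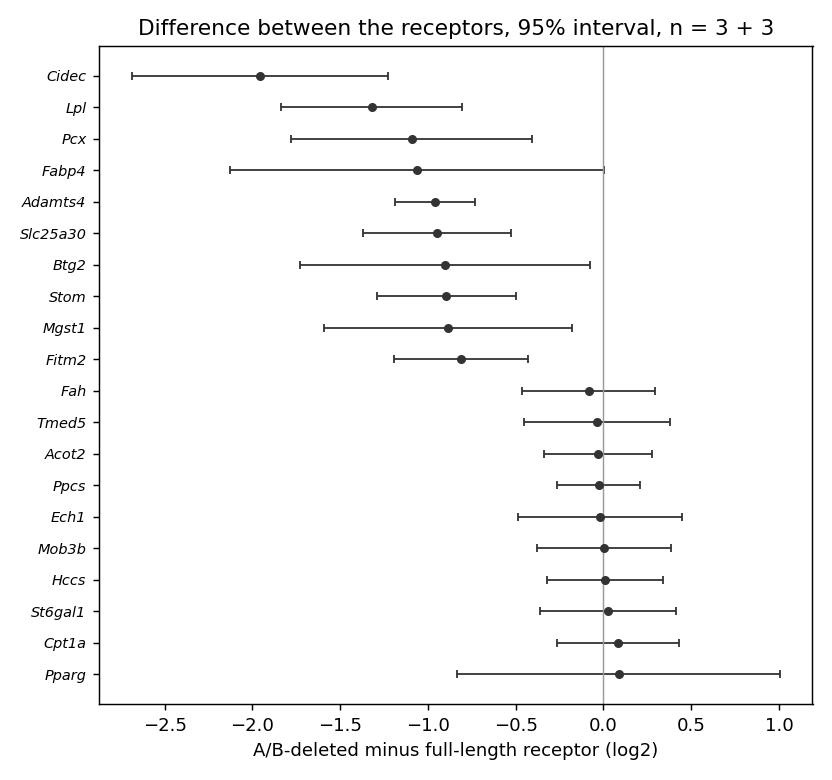
Log2 difference between the deleted and the full-length receptor with its 95% interval from the fit without the block (n = 3 arrays per group) for 20 genes that rose by at least 1 with the full-length receptor, chosen as the 10 largest and the 10 smallest in size of this difference. Cidec (-1.96) and Lpl (-1.32) lie farthest below 0, and Mob3b (0.00) and Hccs (0.01) lie at it. The intervals are not adjusted for this choice of genes.

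Of the genes with the largest differences, Pcx was at -1.09 (-1.78 to -0.41), Fabp4 at -1.06 (-2.13 to 0.01), Slc25a30 at -0.95 (-1.37 to -0.52) and Btg2 at -0.90 (-1.73 to -0.08). Stom was at -0.89 (-1.29 to -0.50), Mgst1 at -0.89 (-1.59 to -0.18) and Fitm2 at -0.81 (-1.19 to -0.43). These intervals come from the fit without the block. The genes were chosen for the size of this difference, and the intervals are not adjusted for that choice. They can therefore leave out 0 by selection, and limma called none of these genes over all genes. With the block the interval of Fabp4, -1.84 to -0.28, no longer held 0, nor did those of Kank3 (-1.10 to -0.23), Pkp2 (-0.54 to -0.08), Ankrd1 (0.02 to 0.89) and Cebpd (0.16 to 0.89). For Fabp4, arrays 1, 2 and 3 read 12.885, 13.154 and 11.043 with the deleted and 13.503, 13.629 and 13.131 with the full-length receptor. Deleted-receptor array 3 therefore carries much of the Fabp4 difference. The difference ran from -1.02 to 0.18 over the 5 probe sets of Slc25a30, from -0.92 to 0.09 over the 6 of Stom and from -0.89 to 0.00 over the 2 of Mgst1. At the other end, Acot2 (-0.03), Ech1 (-0.02), Ppcs (-0.03), Tmed5 (-0.03), Hccs (0.01), Mob3b (0.00), St6gal1 (0.03) and Fah (-0.08) had differences near 0, and the interval of Ech1 was -0.49 to 0.45. The median share of the full-length response kept by the deleted receptor was 76.7% over 57 genes, and 74.6%, 82.1% and 68.1% by replicate number (mean 74.9, SD 6.98). Pparg is counted among these genes, and the share holds any effect of rosiglitazone alone, which both receptor groups received. It was 68.0% without full-length replicate 3 and 68.7% without deleted-receptor replicate 2. Measured in each number over 100 genes chosen without it, a choice made after seeing the data, the shares were 71.3%, 82.5% and 65.6%.

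After the comparison over all genes had called none, the test was restricted to genes higher in the mean of both receptors against empty vector. If arrays were independent and equally variable, this contrast would be uncorrelated with the difference between the receptors. Both use the same estimate of spread for a gene, however, and same-numbered arrays were correlated. The choice can therefore favour genes with a small spread, so p-values within the response genes may be too low. In their deviations, empty-vector arrays correlated with same-numbered deleted-receptor arrays at 0.52 to 0.708, and with full-length arrays at -0.121 to 0.631. A closer link of the controls to the deleted receptor can push the difference of the chosen genes below 0. Sign counts and set p-values of the response genes may therefore overstate the fall, and a held-out measurement is given below. Of these 86 response genes 77 were lower and 9 were higher with the deleted receptor, with a median difference of -0.27 (interquartile range -0.46 to -0.10). Pparg (0.09), whose probe set does not separate transgene from endogenous transcript, is counted among those that were higher. Adjusted over the response genes alone, limma called 13 lower and 0 higher, led by Adamts4 (adjusted p = 0.000378), Lpl (0.00686), the epoxide hydrolase gene Ephx2 (0.00686), Slc25a30 (0.0096), Stom (0.0096), Pde1b (0.0096) and Fitm2 (0.0108). The other 6 were Plk3, Pex13, Adcy6, Myo18a, Get1 and Ermp1, and with Pde1b these were named after their values were seen. As a set the response genes were lower with camera (p = 0.00175 with an estimated correlation) and with fry (p = 0.00184). With the block there were 348 response genes, 299 of them lower, with 71 called lower and 1 higher, Il6 (0.78, adjusted p = 0.00534), named after its value was seen. Among genes named by the rule the block added calls of Cidec (adjusted p = 0.00534) and Pcx (0.022), which were not response genes without it, and of Btg2 (0.1 to 0.022), Cdk18 (0.0708 to 0.0331) and Kank3 (0.22 to 0.0456). With the block the set p was 0.0166 with camera and an estimated correlation and 0.00525 with fry. Of 26 genes lower in the mean of both receptors, 25 were less lowered by the deleted receptor, with a median difference of 0.46 and 0 called by limma. With the block 273 of 287 were less lowered, with a median difference of 0.20 and 23 called. These lowered genes were chosen on the same arrays by the same contrast, which can push their difference above 0. The held-out measurement did not cover them. The count of response genes was 49 without full-length replicate 2, 36 without empty-vector replicate 1, 37 without empty-vector replicate 2, 57 without deleted-receptor replicate 1 and 49 without deleted-receptor replicate 2. The count of 13 was 8 without full-length replicate 1, 6 without full-length replicate 2, 27 without full-length replicate 3, 6 without empty-vector replicate 1, 5 without empty-vector replicate 2, 6 without deleted-receptor replicate 1 and 5 without deleted-receptor replicate 3. Without the arrays numbered 3 it was 20 of 147 response genes.

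By list, the 8 fatty acid oxidation genes among the response genes had a median difference of -0.06 between the receptors, and 0 of them were called with limma. The 3 fatty acid uptake genes were Lpl (-1.32), Fabp4 (-1.06) and Angptl4 (-0.19), of which Lpl was called. The 2 lipid droplet genes were Fitm2 (-0.81), which was called, and Plin2 (-0.18). The 3 oxidative stress genes were Mgst1 (-0.89), Ephx2 (-0.70), which was called, and Aldh9a1 (-0.16). With the block 1 of 19 oxidation, 1 of 4 uptake, 2 of 5 lipid droplet, 2 of 10 oxidative stress, 1 of 3 triglyceride synthesis, 3 of 4 glucose metabolism, 1 of 5 extracellular matrix and 1 of 3 p53 response genes were called lower, and the oxidation genes had a median of -0.06.

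Among the fixed lists, NF-kB and inflammatory genes were higher with the deleted than with the full-length receptor (camera adjusted p = 0.0131; adjusted p = 0.585 with an estimated correlation). No member was called, over all genes or adjusted over the list alone, and 9 of 32 were higher when adjusted over the list alone with the block. The largest differences were those of Cxcl5 (1.32), the cytokine gene Il6 (0.78), Vcam1 (0.67) and the prostaglandin synthase gene Ptgs2 (0.61), of which Il6 and Ptgs2 were chosen after their values were seen. Marker lists of leukocytes (camera adjusted p = 0.0031; adjusted p = 0.663 with an estimated correlation), muscle (camera adjusted p = 0.00862; adjusted p = 0.641 with an estimated correlation) and epithelial and endothelial cells (camera adjusted p = 0.0378; adjusted p = 0.807 with an estimated correlation) were lower, with medians of -0.14, -0.10 and -0.14 and 0 members called, over all genes or adjusted over the list alone. The mean level of the leukocyte list was 6.76 on full-length array 3, the highest of the 9, and between 6.28 and 6.66 on the others. Adjusted over the list alone, 2 lipid droplet, 1 uptake and 1 oxidative stress gene were lower, and 0 of each were called over all genes. With the block and adjusted over the list alone, 2 oxidative stress, 1 triglyceride synthesis and 3 glucose metabolism genes were lower and 1 adipocyte identity and 1 contractile gene were higher. With the block, 5 more lists passed. Uptake (0.0439) and glucose metabolism genes (0.0397) were lower, and cholesterol synthesis (0.045), preadipocyte (0.0152) and contractile genes (0.0193) were higher. None of these was called with an estimated correlation (adjusted p = 0.306, 0.645, 0.792, 0.247 and 0.623 with an estimated correlation and the block). Median subtraction added the brown adipocyte list, lower, from 0.0541 to 0.0335 (adjusted p = 0.369 with an estimated correlation). Fry called 0 lists between the receptors.

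**Figure D4:**
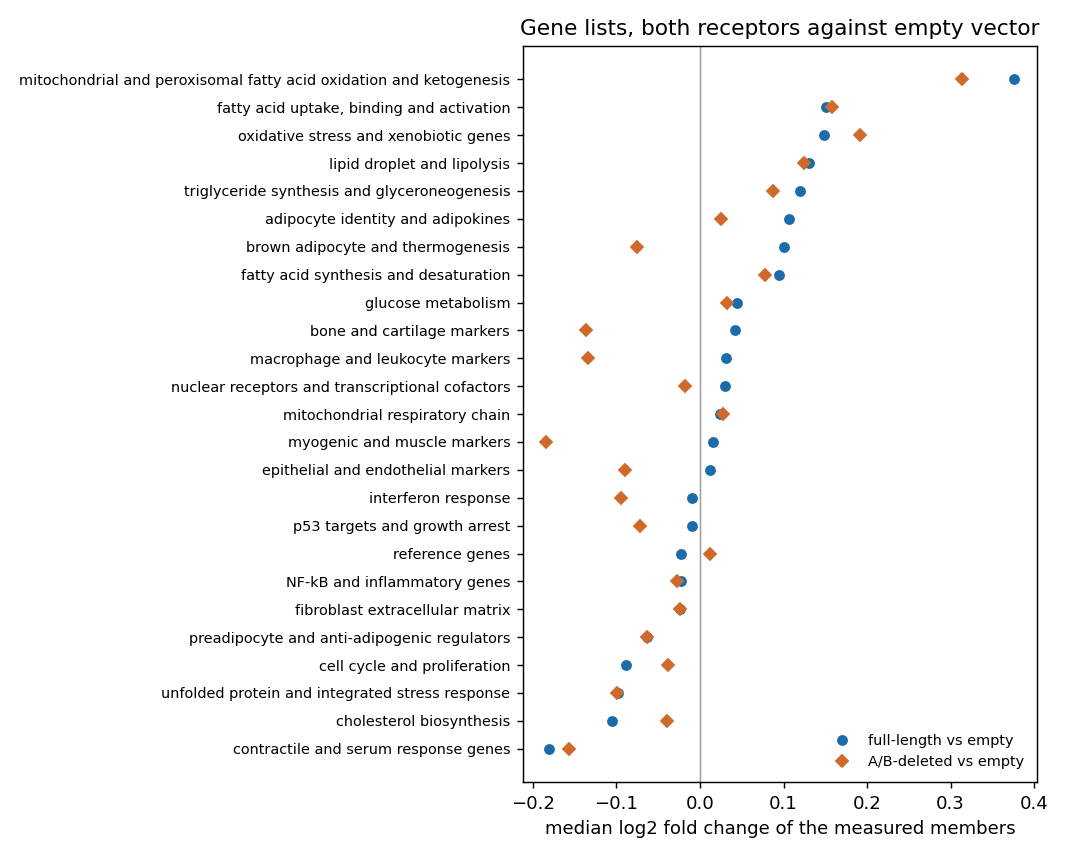
Median log2 fold change of the measured members of 25 gene lists, for the full-length receptor against empty vector and the deleted receptor against empty vector. Fatty acid oxidation genes had the largest medians, 0.38 and 0.31.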

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

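The held-out measurement, the receptor RNA, transferrin receptor, 18S and receptor dose tests below were chosen only after the result was seen, as were the response genes, the splits within a number and the tests of unnamed probe sets.

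Probe sets with no gene name or several, which no comparison used, held 21 that were higher with the full-length receptor and 8 (9 with the block) that were higher with the deleted receptor than with empty vector, of 10092 tested with limma, and 4 were lower, all of them with the full-length receptor. They stand here because no comparison reported on them. The largest increase was 2.652 with the full-length receptor (SE 0.308, adjusted p = 0.00669), and the same probe set was higher by 2.37 with the deleted receptor.

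For 3 arrays against 3 the 10 possible splits are too few for a share under 0.05. For the full-length receptor against empty vector the real split called 119 genes and the highest of the others 0, and 1 of 10 splits gave as many. For the deleted receptor against empty vector these were 31 and 0, again in 1 of 10, and the 3 other splits that part all 3 numbered pairs were among those with 0. For the receptors against each other both were 0 by limma, in 10 of 10. Among response genes the real split called 13 and the highest other 0, in 1 of 10. The F test called 76 genes, and 4 of 100 splits of the 9 arrays gave as many, but these splits exchange arrays freely across numbers. It called 37 without full-length replicate 1, 32 without full-length replicate 2, 26, 23 and 38 without empty-vector replicates 1, 2 and 3 and 39 without deleted-receptor replicate 1. Another split called 1523, and the split by replicate number called 2168, many times the real count, which points to a structure of the arrays by number. That split was not among the 100, so the free splits are not read as excluding chance. When arrays were exchanged only within a number, 1 of 36 splits called as many as the real 76 and the highest other called 30. That share of 0.0278 is the lowest that 36 splits can give. The scheme was chosen after seeing the data, so the share argues against chance but does not exclude it. With the number as a block the F test called 370, against 72 in the highest other of these splits.

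Response genes were lower with the deleted receptor than with the full-length receptor. Choice of genes on the same arrays was argued against: with 100 genes chosen on the other numbers, the mean of the 3 medians was -0.304 ± 0.053 (SD), although the planned choice had given 2, 0 and 90 genes and could not be used, and its values for 2 of the numbers had been seen. The arrays numbered 3 were argued against, because the median without them was -0.25 while numbers 1 and 2 differed by 0.047. Less receptor RNA cannot be told apart, since Pparg differed by 0.087 ± 0.32 (SD of 3 pairs) but its interval, -0.83 to 1.01, holds the response genes' median of -0.27, and with array weights it differed by -0.51. The missing A/B-domain, the difference set by the design, was not tested apart from receptor amount and stays open, and receptor protein was not measured.

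Markers of leukocytes, muscle and epithelial or endothelial cells were lower with the deleted receptor than with the full-length receptor. The leukocyte list's median lay at the 1.37 percentile of 10000 random lists of equal level, beyond the limit set in advance against a shared shift of dim probe sets. That limit was set wrongly, because random lists treat genes as independent while the list's estimated correlation was 0.235, and its adjusted p was 0.663 with an estimated correlation. A shared shift of dim probe sets and other cells therefore cannot be told apart from these values. The cultures are of 1 cell line, and no biological explanation was tested.

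The arrays numbered 3 deviated together from their group means along the first principal component. On the second component full-length array 3 lay apart from the empty-vector and deleted-receptor arrays 3, and what sets it apart was not tested. A different receptor dose was argued against, since the lower of their Pparg values, 10.84, lay inside the range of the other receptor arrays, and the empty-vector array deviated too. RNA degradation cannot be told apart: the lowest beta-actin 3' minus 5' difference, 0.201, met the limit set against it, but beta-actin lay near the top of the scale and decides nothing, and the highest transferrin receptor difference, 1.616, was below the median of the others, 1.776, by less than their SD of 0.287. Another RNA preparation or labelling may be the source, since the highest 18S value among them, 8.672, lay below the lowest of the others, 10.508. No biological explanation was tested.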

How the results depend on the processing

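The fits without the arrays numbered 3, the 100 held-out genes and all tests within response genes were chosen only after the result was seen. Of the summary values under other settings, 269 stayed within their limits, 92 moved and 0 were reversed. For single named genes 1583 values were the same, 113 were no longer past the threshold, 3 newly passed it and 37 uncalled differences changed sign. For list shifts these counts were 240, 37, 11 and 12. The cause was not tested for results that moved, except where fewer genes, fewer arrays or a stricter threshold act by construction. Leaving an array out leaves 2 in its group. The arrays carry no detection calls, so dim genes could not be told from absent ones, which limits what can be read from changes near background.

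With the replicate block the full-length receptor had 344 higher and 317 lower genes against empty vector. Their arrays share only a number (4 of 6 correlated best with their own number). The block gave 120 higher and 46 lower genes for the deleted receptor, 370 in the F test, and 348 response genes, 71 lower and 1 higher with the deleted receptor. Among genes named by the rule and the tests of fixed lists, the block changed no call beyond those given here and in the results. It added 2 list calls for the full-length receptor, NF-kB (adjusted p = 0.0323) and glucose metabolism (0.0193), and neither held (adjusted p = 0.621 and 0.621 with an estimated correlation). Called members of that receptor's lists moved too, for oxidation genes from 5 to 16 higher and for contractile genes from 1 to 4 lower. NF-kB genes went from 2 lower to 1 higher and 7 lower, and extracellular matrix genes from 0 to 5 higher and 4 lower.

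Among genes above the median level 53 were lower with the full-length and 7 with the deleted receptor; with a group mean above log2 6, 21 response genes were lower. Median subtraction gave 1 gene lower with the deleted receptor against empty vector and 7 response genes lower; quantile normalization, cyclic loess and the mean of probe sets each gave 1 lower. Every probe set on its own gave 150 higher and 50 lower (full-length), 45 and 1 (deleted), 120 in the F test and 147 response genes, 20 lower. Trend and robust priors gave 4 lower with the deleted receptor.

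Array weights gave 202 higher and 90 lower (full-length), 60 and 15 (deleted), 2 lower between the receptors, both higher with the full-length receptor, 193 in the F test and 192 response genes, 69 lower. Only the 6 compared arrays gave 53 and 14 (full-length) and 0 lower (deleted). At an adjusted p under 0.01 there were 44 and 10 (full-length), 18 and 0 (deleted), 30 in the F test and 37 response genes, 5 lower; with at least a 1.5-fold change 8 response genes were lower. Without the arrays numbered 3 there were 121 and 35 (full-length), 49 and 6 (deleted) and 147 response genes, 20 lower. Array weights together with the block were left out because the weights did not converge.

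Leaving out 1 array gave 44 to 88 higher and 13 to 26 lower genes with the full-length receptor, 17 to 30 higher and 0 to 4 lower with the deleted receptor, 0 to 1 lower between the receptors, 0 to 1 of these higher with the full-length receptor, 23 to 69 in the F test, 36 to 103 response genes, 5 to 27 lower, and a kept share of 68.0% to 81.2%. The planned held-out share had no gene for number 2 and gave no value. Of 75 list tests camera called 20, fry 5, and camera with an estimated correlation 0.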

Other observations

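The fatty acid oxidation test below was chosen only after the result was seen, and the ERK and peroxisome lists were written after the genes that led to them had been seen, with those genes left out.

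Among response genes, those of fatty acid oxidation differed little between the receptors. The 8 were Acaa2, Acot2, Cpt1a, Cpt2, Ech1, Etfdh, Hadhb and Pdk4, with differences from -0.10 to 0.39 and a median share of 94.6% of the full-length response kept. The other 78 response genes had a median difference of -0.31. The median of the 8 lay at the 99.31 percentile of 10000 random draws of 8 response genes, whose central 95% ran from -0.48 to -0.09. The list was picked, for its small difference, out of 10 that hold a response gene, and the percentile does not pass a limit divided by that number, so the draws do not decide whether oxidation genes were lowered less. Over all 43 measured oxidation genes the median difference was -0.08, with 11 higher and the rest lower with the deleted receptor (camera adjusted p = 0.356), and it lay below all 10000 random lists of equal level, which treat genes as independent.

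Dusp6, Egr1 and Errfi1, genes of ERK feedback and the immediate-early response, fell with the full-length receptor. In a list of 30 other such genes 24 were lower and 6 were higher with the full-length receptor, with a median of -0.19, and Jun (-1.07) was called by limma. The list's p was 0.0733 with an estimated correlation, so a fall of the group was not shown, and a fall cannot be told apart from no change. Pex13 and Pex14, which act in import into peroxisomes, were among the response genes. In a list of 31 other peroxisomal genes 15 were higher and 16 lower, with a median of 0.00 and p = 0.476 with an estimated correlation, and Pex16 was called. A median near 0 over members that went both ways does not decide whether the group rose.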
